A study of Mus musculus with 2 samples.

How the data were processed

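Gene expression was measured in 2 droplet libraries (10x Genomics 3′ chemistry with unique molecular identifiers, UMIs) from mice labelled Shank3-/-. The sample labels give the tissue as brain and the design text as prefrontal cortex. One library came from mice given vehicle and the other from mice given fluconazole, an antifungal azole, in the drinking water for 2 weeks. The labels give 1 library per treatment and do not say how many mice it holds. The study's design text speaks of cells and nuclei together, whereas the extraction text describes nuclei only, so the droplets are called barcodes here. The deposited files are counts per the file headers: whole-number UMI counts per gene and barcode, with no normalization, for barcodes already called as cell-containing, each with at least 500 UMIs. The lists of features are the same in both libraries.

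The matrix header names Cell Ranger 8.0.1, and the authors' notes name Cell Ranger 9.0.0, Seurat 4.0.0, R 4.0.3 and the mm10 genome. Of the 33696 gene identifiers, 31961 are in GENCODE vM21, an annotation of that genome, and 1735 are not, so the annotation used for counting was a later one. No coordinates are therefore given. GENCODE vM21 served to settle repeated symbols and to order genes along chromosomes in 1 test. Aligner settings, the counting of introns and the rule for calling barcodes are not stated.

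Before the data were examined, the filters, marker genes, gene lists, rule for named genes and most alternatives were fixed. Barcodes with at least 500 genes and at most 5% of UMIs from mitochondrial genes were kept. Doublets were called in each library with Scrublet (in scanpy 1.11.5, expected rate 8%), whose own threshold was used because it marked between 0.5% and 25% of barcodes, and were left out. It marked 617 of 14924 vehicle barcodes (4.13%) and 561 of 12637 fluconazole barcodes (4.44%). After both steps 12892 vehicle barcodes (86.4%) and 10572 fluconazole barcodes (83.7%) remained, with 67877915 and 68484369 UMIs.

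Both libraries were clustered together without batch correction. Counts were scaled to 10000 per barcode and logged, 2000 variable genes were chosen per library, and 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 gave 33 clusters (leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15). A cluster took the name of a class when at least 3 of that class's markers were at least 2.0-fold above the other clusters and found in at least 10% of its barcodes. It stayed unnamed where another class scored above 0.4 of the first, where at least 80% of another class's markers were found, where the UMI count was low with no marker among the 10 leading genes, or where leading genes of another class outnumbered its own. Classes that share markers by lineage did not count against each other, and the higher score named the cluster: GABAergic neurons, striatal spiny neurons and neuroblasts; the stages of oligodendrocytes; microglia and border macrophages; mural cells and fibroblasts. The markers were fixed beforehand, but these naming rules, and 1 for mixed blood cells, were written with the clusters at hand. By these rules 28 clusters were named and 5 stayed unnamed. Classes with at least 50 barcodes in each library were compared, which gave 12 classes. Class names rest on marker genes alone, and the same expression data made the clusters, so the markers of a class are not reported as what defines it. Markers of other classes do occur among the ranked genes and are named as such.

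UMIs were summed over the barcodes of a class and library and scaled to a common total per class and library (CPM). The comparison throughout is the log2 ratio of fluconazole over vehicle CPM. Because each treatment has 1 library, no test between treatments was made and no p-value or count of changed genes is given: barcodes of a library are not replicates. Intervals are at 95% and cover counting error only: exact Clopper-Pearson binomial intervals for shares, exact Poisson intervals for CPM and exact conditional binomial intervals for ratios. They leave out differences between mice, dissections and libraries. Those for CPM and ratios treat every UMI as an independent draw, so they also leave out differences between barcodes of a library. Where the UMIs of a gene lie in few barcodes, the interval is too narrow. A gene at 0 in a library was given a bound against 3 counts in that library's class.

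For the 22 gene lists, members with at least 20 UMIs over both libraries in the class were used. A list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression in 20 bins, and its percentile describes these 2 libraries only. Its interval comes from 1000 Poisson draws of the counts and has the same limits. A list with genes of higher and lower CPM is given with both numbers. The lists cover cholesterol biosynthesis, sterol uptake and transport, lipid rafts and sphingolipids, IGF1 receptor signalling, the MAPK cascade, postsynaptic scaffolds, glutamate receptors, GABA receptors, presynaptic release, immediate early genes, voltage-gated channels, autism-associated regulators, myelin, microglial activation, reactive astrocytes, interferon response, heat shock, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, nuclear-retained RNAs and sex-linked genes. 3 further lists, of glucocorticoid-induced genes and of the evening and morning arms of the clock, were written after the ranked genes had been seen.

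The rule for named genes took, in glutamatergic neurons, the 10 genes with the highest lower bound and the 10 with the lowest upper bound of the ratio's interval, among genes with at least 100 UMIs over both libraries. In every other class it took 3 in each direction, and of each list up to 2 in each direction. Shank3, Igf1r and Cyp51 were always named. Mitochondrial, ribosomal, sex-linked and haemoglobin genes and gene models with Gm or Rik symbols were left out of the rankings, and some of them are given as checks. Other genes named below are members of the lists or were chosen after their values were seen, as stated.

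Alternatives changed 1 step at a time, and the barcode filters changed both of their thresholds together. They were a looser barcode filter (200 genes, 10%), a stricter one (1000 genes, 1%), doublets kept, Leiden resolutions of 0.5 and 2.0, components centred per library, a denominator of named classes, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors, barcodes thinned to 1500 UMIs, an unweighted mean over clusters, a correction for free RNA, and other count minimums (50 and 500 UMIs for ranked genes; none with a pseudocount of 0.5, or 100, for lists). Thinning was 1 random draw per barcode. Its values have no interval of their own and were compared with the interval of the full counts. Leaving out glutamatergic cluster 17, adding the low-UMI clusters to the class of their markers, and leaving out the barcode with most UMIs of a gene were added after the data had been seen. The free-RNA share was the median over pairs of a class and the markers of another class, 15.8% in the vehicle library and 14.1% in the fluconazole library. It is a rough figure, since some pairs share expression and exceed 100%. The correction took this share of each library's pooled counts from every class. As the vehicle share is larger, it can raise the ratio of genes scarcer in a class than in the pool. A change of sign under it therefore does not decide where a transcript came from.

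The calculation of ratios, intervals and list percentiles was tested on simulated data drawn from the glutamatergic class with 200 altered genes. Apart from these, both libraries were drawn by Poisson counting from shared rates, as the intervals assume. Coverage near 95% was therefore bound to follow. Differences between barcodes or libraries were not simulated, so the test does not cover them. In this simulation 95.5% of the unaltered among 14309 genes had the true ratio inside the interval. The interval lay on the true side of no change for 78.0% of genes altered 1.25-fold and for all of those altered 2.0-fold. In a like simulation of microglia with 11558 genes these shares were 66.0% and 98.0%, and 95.4% of unaltered genes had the true ratio inside the interval. Of 100 random unaltered lists, 94 in the glutamatergic and 96 in the microglial simulation lay in the central 95% of percentiles. Figures were drawn with matplotlib 3.10.9.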

Results

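The data are 2 libraries of single barcodes from mice labelled Shank3-/-, whose tissue is brain in the sample labels and prefrontal cortex in the design text, 1 from mice given vehicle and 1 from mice given fluconazole in drinking water for 2 weeks. Shank3 encodes a scaffold protein of excitatory synapses. The study's title names lipid rafts, the IGF1 receptor and prefrontal circuits, so the comparison asks how transcripts of those systems, and of each cell class, stand in the 2 libraries. The vehicle library held 14924 deposited barcodes with 76891692 UMIs, and the fluconazole library 12637 barcodes with 78380009 UMIs. Among kept barcodes the median was 4327 UMIs and 2111 genes in the vehicle library, against 5244 UMIs and 2388.5 genes in the fluconazole library. Thinned to 1500 UMIs, the medians were 982 and 983 genes. Mitochondrial UMIs had a median of 1.29% and 1.44%. Neither treatment has a replicate, so every difference below is between 2 libraries, and its interval covers counting error only.

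Microglia, endothelial cells and glutamatergic neurons made up most of both libraries. Microglia were 25.3% of vehicle barcodes (95% interval 24.5 to 26.0) and 24.0% of fluconazole barcodes (23.2 to 24.9). Endothelial cells were 22.2% (21.5 to 22.9) and 26.0% (25.2 to 26.9), and glutamatergic neurons 16.7% (16.0 to 17.3) and 16.0% (15.3 to 16.7). Neuroblast-like cells, a class found outside the cortex, were 3.40% (3.09 to 3.73) of vehicle and 1.65% (1.41 to 1.91) of fluconazole barcodes, a ratio of 0.484 (0.404 to 0.579). Spiny neurons of striatal type, also from outside the cortex, were 2.45% and 1.90%. Fibroblasts were 2.02% and 1.45%, oligodendrocyte precursors 1.41% and 1.07%, and mural cells 3.89% and 4.76%. Astrocytes (6.11% and 6.27%), oligodendrocytes (4.49% and 4.31%), GABAergic neurons (3.78% and 3.75%) and border macrophages (1.17% and 1.21%) had share ratios whose intervals include 1.0.

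With the stricter barcode filter the endothelial ratio turned from 1.17 to 0.869. That filter allows at most 1% mitochondrial UMIs, whereas the endothelial medians were 2.37% in the vehicle and 2.62% in the fluconazole library. It therefore left out most endothelial barcodes, and its ratio describes the remainder only. Unnamed clusters held 7.15% and 7.61% of barcodes. They comprise 2 clusters of low UMI count with oligodendrocyte or glutamatergic markers, a cluster with mural and endothelial markers, a red blood cell cluster and a cluster of mixed blood leukocytes. The blood leukocyte cluster was 1.86% of vehicle and 0.917% of fluconazole barcodes, and only 28.8% of its barcodes came from the fluconazole library, against 45.1% of all kept barcodes. The neuroblast cluster (28.4%) and 1 glutamatergic cluster (32.3%) also drew few barcodes from the fluconazole library. The chemokine and cytokine genes Ccl4, Ccl3, Il1a and Tnf led 1 of the microglial clusters, which took 45.0% of its barcodes from the fluconazole library.

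**Figure D1:**
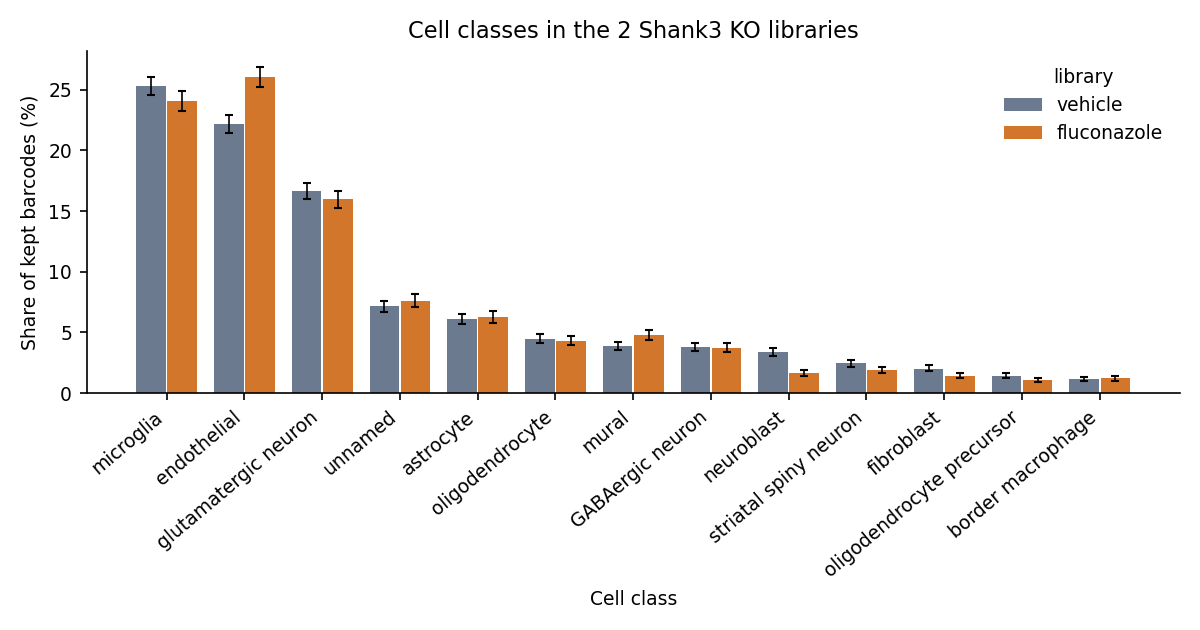
Share of kept barcodes (%) per cell class in the vehicle and the fluconazole library; bars are shares and whiskers exact 95% binomial intervals, which cover counting error only. Endothelial cells stood at 22.2% and 26.0%, and neuroblast-like cells at 3.40% and 1.65%.

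Shank3 transcripts were counted in both libraries although the mice are labelled as knockouts. Where these tags lie in the gene was not analysed here, and the labels do not state the deleted part, so the knockout is not checked by these counts. In glutamatergic neurons Shank3 stood at 70.6 CPM (67.0 to 74.3) in the vehicle and 78.6 CPM (74.9 to 82.4) in the fluconazole library, a log2 ratio of 0.16 (0.05 to 0.26). Endothelial cells had 116 and 114 CPM (-0.03, -0.14 to 0.08), GABAergic neurons 59.1 and 53.4 CPM (-0.15, -0.50 to 0.20) and microglia 2.42 and 2.27 CPM. Shank3 had a UMI in 44.6% of vehicle and 55.7% of fluconazole glutamatergic barcodes, at median depths of 8105.5 and 11389.5 UMIs, and in 1.14% and 1.30% of microglial barcodes, at 4545 and 5896 UMIs. Igf1r, the receptor of insulin-like growth factor 1, stood at 236.5 CPM (229.9 to 243.2) and 257.4 CPM (250.7 to 264.2) in glutamatergic neurons, a log2 ratio of 0.12 (0.07 to 0.18), and 0.06 after correction for free RNA. In endothelial cells, where it was most abundant, Igf1r stood at 1970 CPM (1943 to 1996) and 2545 CPM (2516 to 2574), 1.29-fold (1.27 to 1.31) higher in the fluconazole library. Igf1r was also higher in microglia (log2 ratio 0.21, 0.14 to 0.28) and lower in astrocytes (-0.18, -0.34 to -0.02).

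Cyp51, the mammalian counterpart of the fungal enzyme that fluconazole blocks, acts in cholesterol synthesis. In glutamatergic neurons it stood at 32.0 CPM (29.6 to 34.5) and 34.4 CPM (31.9 to 36.9), a difference within counting error (log2 ratio 0.10, -0.05 to 0.26). With thinned barcodes the log2 ratio was 0.53, from lower counts and without an interval of its own. In oligodendrocytes, the class with the highest vehicle CPM, it was 123 CPM (113 to 134) and 98.0 CPM (89.0 to 108), a log2 ratio of -0.33 (-0.51 to -0.15).

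Among the 20 ranked genes of glutamatergic neurons, Tmem267, a membrane protein gene, stood furthest apart. It had 12674 UMIs (613 CPM) in the vehicle and 177 UMIs (8.16 CPM) in the fluconazole library, 75.1-fold lower, in 1805 and 145 barcodes. The unnamed gene ENSMUSG00000095041 was 5.94-fold lower (720.6 and 121 CPM). The genes higher in the fluconazole library were led by the glycosyltransferase gene B4galnt3, 2.82-fold (2.06 to 3.92), and Serinc2, 2.33-fold (1.97 to 2.77), followed by Spag16, Sgsm1, Foxo6, Galnt9, Xkr7, Etv5, Tesc and Ccn4, with log2 ratios from 0.99 to 1.48. Etv5, an ETS transcription factor of growth factor pathways, stood at 56.2 and 111 CPM (log2 ratio 0.99, 0.88 to 1.09). Sgsm1 stood at 38.0 and 81.1 CPM (1.09, 0.97 to 1.22) and Galnt9 at 36.9 and 76.8 CPM (1.06, 0.94 to 1.19). Among gene models left out of the ranking, Gm17167 was 6.73-fold lower (57.1 and 8.48 CPM) and 4921511C10Rik 2.37-fold higher (54.9 and 130 CPM).

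Several of the lower genes belong to other cell types. The neutrophil genes S100a9 and S100a8 had log2 ratios of -3.84 and -3.61, and 36.8% and 41.6% of their vehicle UMIs lay in 1 barcode. The antigen presentation genes Cd74, H2-Aa, H2-Eb1 and H2-Ab1 lay between -2.24 and -2.06, and with doublets kept they turned to between 0.19 and 0.56. Igfbpl1 (-1.86) is a gene of neuroblasts and Dlx6os1 (-1.29) a marker of GABAergic neurons. The glutamatergic clusters drew from 32.3% to 50.4% of their barcodes from the fluconazole library. Of the 20 ranked genes, 11 stayed ranked with an unweighted mean over clusters, 5 with thinned barcodes and 3 after correction for free RNA. Thinning lowers the counts of genes while the minimum count for ranking stays the same. With a minimum of 500 UMIs and no thinning, 9 of the 20 stayed ranked. The number left after thinning therefore cannot tell low counts from changed ratios.

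**Figure D2:**
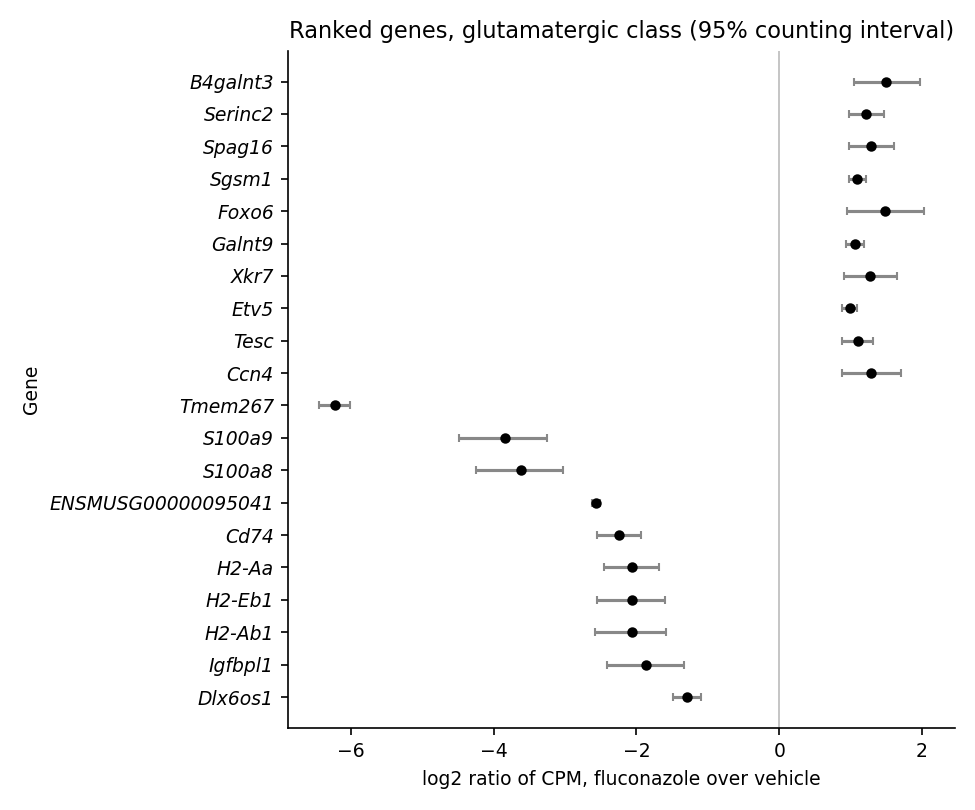
log2 ratio of CPM, fluconazole over vehicle, for the 20 ranked genes of glutamatergic neurons; points are ratios and whiskers exact 95% intervals for counting error. Tmem267 lies at -6.23, and the higher genes start at 0.99 (Etv5).

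Of the 22 cholesterol biosynthesis enzymes, 3 had higher and 19 lower CPM in the fluconazole library in glutamatergic neurons, with a median log2 ratio of -0.15 (-0.24 to -0.09) at percentile 4.76 of matched random lists. Lss, lanosterol synthase, stood at -0.44 (-0.72 to -0.17) and Hmgcs1, an early enzyme of the pathway, at -0.31 (-0.46 to -0.17). In oligodendrocytes 9 were higher and 13 lower, with a median of -0.14 (-0.20 to -0.01) at percentile 0.13, led by Hmgcs1 (-0.43, -0.56 to -0.31) and Idi1 (-0.38, -0.60 to -0.16). The median was 0.21 (-0.21 to 0.41) in spiny neurons of striatal type, 0.05 (-0.08 to 0.31) in GABAergic neurons and -0.02 (-0.09 to 0.11) in endothelial cells. Of the 24 genes of sterol uptake and transport, 9 were higher and 15 lower in glutamatergic neurons (median -0.10, percentile 10.6). Nr1h3, a sterol-sensing receptor, stood at 1.19 (0.53 to 1.88) from 28 and 67 UMIs, Lrp8 at 0.26, Npc2 at -0.46 and the lipid exporter Abca1 at -0.42. Ribosomal protein transcripts, a measure of cytoplasmic RNA, were lower in glutamatergic neurons as well. In oligodendrocytes 62 of 81 were lower, by less (median -0.05).

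Lipid raft scaffolds and sphingolipid enzymes showed no common direction in glutamatergic neurons: 12 of 28 were higher and 16 lower, with a median of -0.02 (-0.07 to 0.04) at percentile 59.9. The ganglioside sialyltransferase St8sia5 was 1.73-fold higher (log2 ratio 0.79, 0.68 to 0.90) and Cers1 stood at 0.29. Ugt8a, an enzyme of galactosylceramide synthesis abundant in oligodendrocytes, stood at -0.71 and the caveolar gene Cavin1 at -0.51. With median-of-ratios factors or thinned barcodes the raft median was 0.05. Cers1 and Cavin1 changed sign with thinned barcodes, whose lower counts were given no interval.

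Of 39 measured genes of IGF1 receptor and insulin to mTOR signalling, 20 were higher and 19 lower in glutamatergic neurons, with a median of 0.01 (-0.03 to 0.04) at percentile 82.1. Besides Igf1r, the adaptor Shc3 was higher (0.39, 0.31 to 0.47). Igfbp5 stood at -0.99 (-1.31 to -0.68) and Eif4ebp1, a repressor of translation under mTOR, at -0.95 (-1.37 to -0.55). Of 23 genes of the MAPK cascade, 13 were higher and 10 lower, with a median of 0.03 (-0.04 to 0.06) at percentile 87.8. Spred1, an inhibitor of the cascade, stood at 0.70 (0.62 to 0.77) and Dusp4, a MAP kinase phosphatase, at 0.85 (0.18 to 1.56). Dusp1, another phosphatase, stood at -0.45, and Mapk3 at -0.52 but at 0.09 with thinned barcodes.

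Postsynaptic density scaffolds were the synaptic list with the highest median in glutamatergic neurons: 18 of 26 were higher and 8 lower, with a median of 0.14 (0.09 to 0.18) at percentile 99.99, and the summed list stood at 0.03. Nuclear-retained RNAs were also higher and ribosomal proteins lower in these barcodes. Homer1, which binds Shank proteins and has a short activity-induced form, stood at 231 and 430.5 CPM (0.90, 0.85 to 0.95), and Dlgap3 at 0.46 (0.39 to 0.54). Homer1 was higher by at least 0.5 in 4 of 11 measured classes, border macrophages among them, and lower by as much in none. Cnksr2 (-0.17) and Dlg1 (-0.09) were lower. Glutamate receptor genes split evenly (13 and 13, median 0.00, -0.03 to 0.02, percentile 52.6), with Cacng2 at 0.52, Grik3 at 0.48, Grm2 at -0.76 and Grm8 at -0.24. GABA receptor genes had 6 higher and 11 lower members (median -0.08, percentile 1.87), with both subunits of the GABA-B receptor higher (Gabbr2 0.33, Gabbr1 0.31) and Gabrg1 (-0.81) and Gabra2 (-0.34) lower. Presynaptic genes had 16 higher and 10 lower members (median 0.05, percentile 94.2), with Cplx2 at 0.60, Bsn at 0.33, Syt1 at -0.20 and Rims2 at -0.13.

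Immediate early genes, which follow neuronal activity, had 6 higher and 17 lower members (median -0.25, -0.36 to -0.16, percentile 0.0). Fos (-0.45, -0.52 to -0.38) and Ier2 (-0.47) were lower, whereas Arc (0.94, 0.61 to 1.27), Nr4a2 (0.89, 0.63 to 1.16) and Bdnf (0.50) were higher. The median turned to 0.09 after the rough correction for free RNA. Voltage-gated channels had 18 higher and 13 lower members (median 0.00, percentile 55.5), with Cacna1g at 0.40, Scn3a at -0.40 and Kcnb2 at -0.28. Autism-associated chromatin and transcription regulators split 10 and 10 (median 0.00, percentile 41.5), with Bcl11a at 0.34, Myt1l at 0.17, Tcf4 at -0.16 and Setd5 at -0.07.

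The lists set as checks of cytoplasmic RNA, of ribosomal proteins and mitochondrially encoded genes, were lower in glutamatergic neurons. Oxidative phosphorylation and heat shock genes were lower as well. Ribosomal proteins had 80 of 81 members lower (median -0.41, -0.43 to -0.38), nuclear-encoded oxidative phosphorylation 79 of 82 (-0.26, -0.29 to -0.21), heat shock and unfolded protein genes 17 of 18 (-0.33, -0.41 to -0.26) and mitochondrially encoded genes 12 of 13 (-0.15, -0.24 to -0.11). Ndufa13 stood at -0.63, Hspa1b at -1.62 and mt-Atp6 at -0.29, whereas Hsph1 (0.40) and mt-Nd1 (0.34) were higher. The heat shock median turned to 0.46 after the rough correction for free RNA. Nuclear-retained RNAs had 7 of 8 members higher (median 0.09, 0.06 to 0.13), with Malat1 at 0.18 and Neat1 at -0.39. Transcripts of other cell types were lower too: microglial C1qa, C1qb and C1qc summed to 407.5 and 295 CPM. A barcode nevertheless held 3.92 and 3.79 of their UMIs on average, at median depths of 8105.5 and 11389.5 UMIs. In glutamatergic barcodes the microglial activation list (median -0.51), the myelin list (-0.30) and the reactive astrocyte list (-0.24) were lower, while the interferon list (-0.09, -0.37 to 0.03, percentile 51.1) lay within counting error. Of the sex-linked genes, Xist had 16 and 27 UMIs over all barcodes and the Y-linked Ddx3y 7848 and 7237 UMIs.

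**Figure D3:**
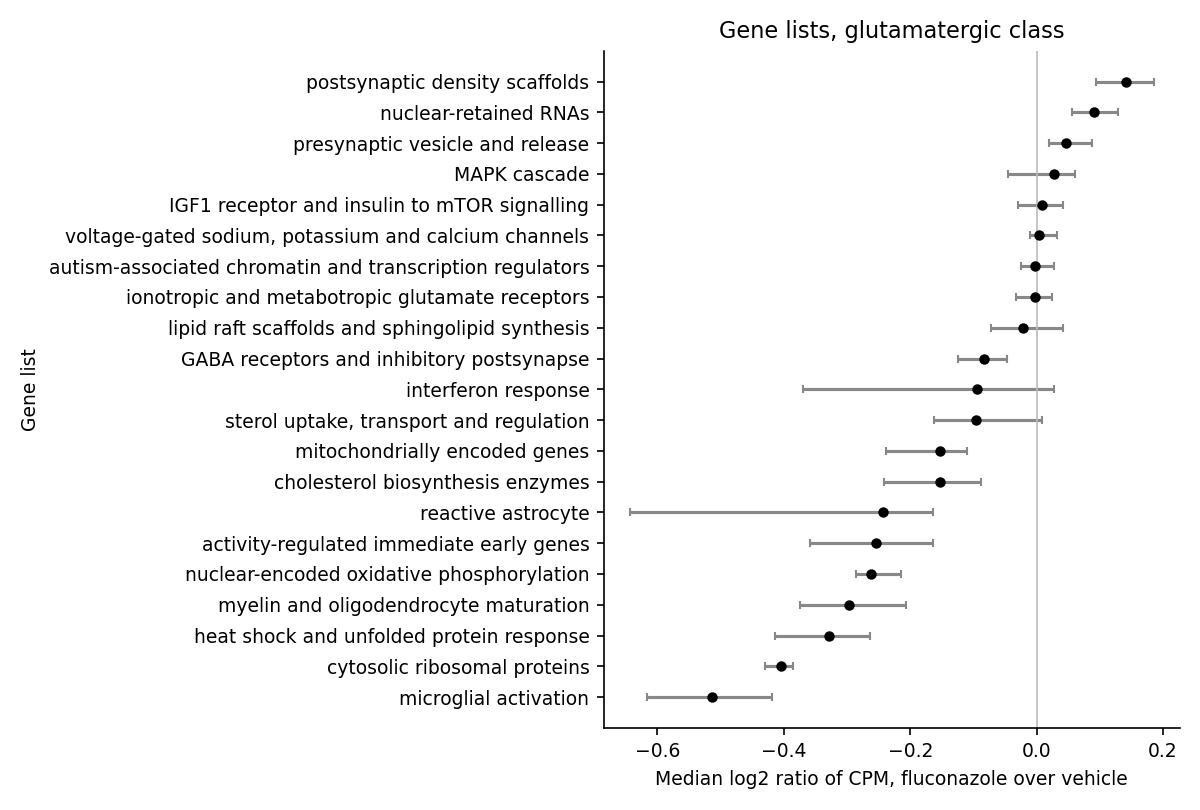
Median log2 ratio of CPM, fluconazole over vehicle, for the gene lists in glutamatergic neurons; whiskers are 95% intervals from Poisson draws of the counts. Postsynaptic scaffolds lie at 0.14, cholesterol biosynthesis at -0.15 and ribosomal proteins at -0.41.

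In endothelial cells the transcription factor gene Zbtb16 was 4.06-fold higher in the fluconazole library (49.0 and 199 CPM, log2 ratio 2.02, 1.88 to 2.16), in 391 and 1169 barcodes. Angptl4, a secreted inhibitor of lipoprotein lipase, was 2.97-fold higher (1.57, 1.26 to 1.88) and the iron-binding lipocalin gene Lcn2 2.72-fold higher (1.44, 1.23 to 1.67). Hebp1 was 4.28-fold lower (-2.10, -2.35 to -1.86) and the endothelial cadherin gene Pcdh12 4.13-fold lower (-2.05, -2.68 to -1.46). Ttr, a choroid plexus gene, had 816 vehicle UMIs, 82.8% of them in 1 barcode, and none in the fluconazole library. In mural cells Pik3r3 (1.06), Gclm (1.20) and Lin7a (0.69) were higher, and the elastin gene Eln (-1.56) and C1qb (-1.67), a microglial gene, were lower. Ttr, at 123 and 0 UMIs, was at least 51.4-fold lower, with 97.6% of its UMIs in 1 barcode.

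In oligodendrocytes Sgk1, a kinase gene induced by corticosteroids, stood at 140 and 575 CPM, 4.11-fold higher (2.04, 1.91 to 2.17), and Zbtb16 was 3.43-fold higher (1.78, 1.56 to 1.99). The phosphodiesterase gene Pde4d was 2.43-fold lower (-1.28, -1.45 to -1.12), as were Nalf1 (-1.40, with 63.4% of vehicle UMIs in 1 barcode) and Tubb2b (-1.51). Tnr, a marker of oligodendrocyte precursors, stood at 2.11 with 79.5% of its fluconazole UMIs in 1 barcode, and at -0.08 without that barcode. Of 15 myelin genes 4 were higher and 11 lower (median -0.04, -0.06 to -0.01, percentile 17.6), with Myrf at 0.20 and Ugt8a at -0.36 (-0.42 to -0.31). The median turned to 0.04 with doublets kept. In oligodendrocyte precursors S100a6 (1.83), Cxcl12 (1.38) and Spock2 (1.10) were higher, the last 2 of which turned negative with the stricter filter, and Tmem267 (-4.33), Galntl6 (-2.39) and ENSMUSG00000095041 (-1.76) were lower. Cxcl12 is a leading gene of 1 endothelial cluster.

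In microglia interferon response genes were lower in the fluconazole library: 15 of 15 had lower CPM, with a median log2 ratio of -0.89 (-1.38 to -0.71) at percentile 0.0. Ifit1 stood at -1.84 (-2.59 to -1.14) and Usp18 at -1.77 (-2.28 to -1.29), and the summed list at 364 and 250.0 CPM. The list was also lower in border macrophages (12 of 14, median -1.01, -1.32 to -0.60), mural cells (12 of 12, -0.75, -1.04 to -0.38) and endothelial cells (15 of 15, -0.27, -0.33 to -0.22), and higher in fibroblasts (8 of 11, 0.47, 0.19 to 1.01). In mural barcodes microglial C1qa, C1qb and C1qc were lower too (-1.42, -1.62 to -1.22), as were 75 of 81 ribosomal proteins (median -0.16). In endothelial barcodes these C1q genes stood at -0.43 (-0.51 to -0.35), although the ribosomal median was 0.01. In border macrophages 73 of 81 ribosomal proteins were lower (median -0.15). Phgdh, the first enzyme of serine synthesis, was 2.54-fold higher in microglia (1.34, 1.18 to 1.51), followed by Fcrl1 (1.21, 0.99 to 1.44) and Tex11 (1.36, 0.72 to 2.03). Pianp stood at -2.06, S100a9 at -2.72 and Ttr at -6.83 (-12.15 to -4.33) from 116 and 1 UMIs, 66.4% of the vehicle UMIs in 1 barcode. Of 21 microglial activation genes 6 were higher and 15 lower (median -0.08, -0.17 to -0.07, percentile 0.98), with Cd9 at 0.26, Ccl3 at 0.10, H2-Aa at -1.38 and H2-Ab1 at -1.05. In border macrophages Fkbp5, a glucocorticoid-induced chaperone gene, was 3.34-fold higher (1.74, 1.21 to 2.31), followed by Homer1 (1.39) and Eps8 (0.92). H2-Ab1 (-1.59), H2-Eb1 (-1.36) and Fabp5 (-1.84, with 54.5% of vehicle UMIs in 1 barcode) were lower there.

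In astrocytes Zbtb16 was 2.66-fold higher (1.41, 0.93 to 1.92) and the laminin gene Lama3 1.46-fold higher (0.55, 0.36 to 0.73). Npy, a neuropeptide gene and marker of GABAergic interneurons, had 403 UMIs in 22 vehicle barcodes and 3 UMIs in the fluconazole library (-7.17, -9.46 to -5.61), and Tmem267 (-4.55) and Apod (-3.30) were lower. Cdh18, a leading gene of 1 glutamatergic cluster, stood at 1.07 with 45.7% of its fluconazole UMIs in 1 barcode, but at -1.67 with the stricter filter. Of 8 measured reactive astrocyte genes 8 were lower (median -0.33, -0.58 to -0.12, percentile 1.19), with Vim at -0.60 and C4b at -0.80 but at 0.04 with thinned barcodes. In the same barcodes ribosomal proteins were lower in 81 of 81 members (median -0.44, -0.48 to -0.41), and microglial C1qa, C1qb and C1qc summed to 677 and 399 CPM (-0.76, -0.88 to -0.64). In GABAergic neurons Cadps2 (1.05), Col14a1 (1.31) and Vtn (1.60), a marker of mural cells with 27.2% of its fluconazole UMIs in 1 barcode, were higher and Tmem267 (-6.58, -7.31 to -5.93) was lower. The mast cell genes Mcpt4 and Cma1, at least 52.9-fold and 51.0-fold lower there, had 99.3% and 100.0% of their vehicle UMIs in 1 barcode.

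In neuroblast-like cells Tenm1 (1.18, with 46.3% of fluconazole UMIs in 1 barcode), Brinp1 (0.83) and Cdh8 (1.02) were higher and Ccl3 (-2.06), Epha6 (-1.71) and Egfem1 (-1.64) lower. Ccl3 is a leading gene of 1 microglial cluster. In spiny neurons of striatal type Ntm stood at 1966 and 4419 CPM (1.17, 1.11 to 1.23), with Vcan (1.65), a marker of oligodendrocyte precursors, and Nckap5 (1.58, with 54.1% of fluconazole UMIs in 1 barcode) also higher. Tmem267 (-6.68), ENSMUSG00000095041 (-2.26) and the serotonin receptor gene Htr4 (-1.82) were lower. In fibroblasts Col8a1 (1.44) was higher and Tmem267 (-5.79), Adamts1 (-2.10) and Igfbp5 (-1.62) lower. Igfbp5 turned to 0.37 with the looser filter. Asic2 stood at 1.68, with 49.1% of fluconazole UMIs in 1 barcode, and Ptpro, a leading gene of 1 microglial cluster, at 1.34 there. With the stricter filter Asic2 was -0.20, and with thinned barcodes Ptpro was -0.51.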

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

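Unnamed clusters took no part in the comparison of classes, and comparing their shares with the vehicle library was chosen after the shares had been seen. The cluster with markers of both mural and endothelial cells held 1.62% of fluconazole barcodes (1.39 to 1.88), above the vehicle library's 1.11% (0.936 to 1.30). The cluster of low UMI count with glutamatergic markers held 1.40% of fluconazole barcodes (1.19 to 1.64), above 0.915% (0.758 to 1.09) in the vehicle library. Both were singled out because the fluconazole interval lay above the vehicle interval. No explanation was tested for either, and the intervals cover counting error only.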

How the results depend on the processing

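No paired analysis was possible because each treatment has 1 library. The settings that left out cluster 17, added low-UMI clusters or dropped a gene's top barcode were chosen after seeing the data, and the cause of the shifts below was not tested. A change of sign was counted only where the reported interval lay wholly on 1 side of no change. Over all settings, 1250 values of the 165 named results, each a gene in a class, lay inside the reported interval. Another 237 lay outside it without a counted change of sign, and 16 had a counted change. For 25 list medians these numbers were 226, 57 and 3, and for 12 share ratios 87, 5 and 1. Changes of sign from an interval that included no change are not in these counts. The glutamatergic raft median, for example, went from -0.02 to 0.048 with median-of-ratios factors. Interferon response in microglia kept its direction in every setting run, as did Tmem267 in glutamatergic neurons and Zbtb16 in endothelial cells. The stricter filter gave no value for border macrophages, mural cells and oligodendrocytes, and some named genes had too few counts to be thinned or corrected.

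The looser filter kept 14034 vehicle and 11780 fluconazole barcodes (medians 4171 and 4942 UMIs), and Igfbp5 in fibroblasts was 0.37. The stricter filter kept 4796 and 3761 (5356.5 and 7032 UMIs). It left out most endothelial cells, microglia and neuroblasts, whose medians of mitochondrial UMIs lay above its bound of 1% in both libraries. With it the share ratios were 1.35 for astrocytes, 0.869 for endothelial cells, 0.977 for fibroblasts, 1.03 for glutamatergic neurons, 0.878 for microglia and 0.580 for neuroblasts. It also gave Cdh18 in astrocytes -1.67, Asic2 in fibroblasts -0.20, and Cxcl12 -1.69 and Spock2 -0.22 in oligodendrocyte precursors.

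With doublets kept, glutamatergic Cd74 was 0.19, H2-Aa 0.21, H2-Eb1 0.43 and H2-Ab1 0.56, Tnr in oligodendrocytes -0.073 (-0.085 without its top barcode) and the myelin median 0.042. Of the 20 ranked glutamatergic genes, 13 remained with doublets kept, 11 with the mean over clusters, 9 with a minimum of 500 UMIs, 5 with thinned barcodes and 3 with the free-RNA correction. Thinning lowers counts against an unchanged minimum for ranking, so the 5 cannot tell low counts from changed ratios.

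In glutamatergic neurons, TMM factors gave medians of 0.053 for IGF1 receptor signalling and 0.19 for postsynaptic scaffolds. Median-of-ratios factors gave -0.084 for cholesterol biosynthesis, 0.048 for rafts, 0.077 for IGF1 receptor signalling and 0.21 for scaffolds. These factors shifted all glutamatergic ratios by 0.04 and 0.07. Thinned barcodes gave 0.046 for rafts, 0.043 for IGF1 receptor signalling, 0.53 for Cyp51, -0.10 for Cers1, 0.15 for Cavin1 and 0.092 for Mapk3. Thinning also gave Igf1r over all barcodes 0.48, Ptpro in fibroblasts -0.51 and C4b in astrocytes 0.037. These values come from 1 random draw with lower counts and have no interval. For genes with few counts they cannot tell counting error from changed ratios. The free-RNA correction gave 0.047 for IGF1 receptor signalling, 0.058 for Igf1r, 0.088 for immediate early genes and 0.46 for heat shock.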

Other observations

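The free-RNA tests of Zbtb16 and Tmem267, both tests of neighbouring genes and the test by microglial cluster shares were chosen after results had been seen in part, and the glucocorticoid and clock lists after the ranked genes but before the lists' own values. Several lists pointed different ways in different cell classes, though the differences between classes were not tested. Immediate early genes were lower in GABAergic neurons (15 of 18 members, median log2 ratio -0.79, -0.89 to -0.65) and astrocytes (17 of 18, -0.54, -0.62 to -0.35), near 0 in endothelial cells (-0.01, -0.04 to 0.03) and higher in border macrophages (14 of 18, 0.15, 0.08 to 0.19). Microglial C1qa, C1qb and C1qc were lower in the same GABAergic barcodes (-1.24, -1.36 to -1.11), and a correction for free RNA turned the immediate early median of glutamatergic neurons to 0.09. That correction is rough and takes a larger share from the vehicle library, so the change of sign does not decide the source of these transcripts. Heat shock genes were lower in astrocytes (17 of 17, -0.38) and fibroblasts (16 of 18, -0.42) and had 14 of 17 members higher in oligodendrocyte precursors (0.12, -0.03 to 0.32). Oxidative phosphorylation genes were lower in fibroblasts (68 of 80, -0.38, -0.49 to -0.31) and higher in oligodendrocyte precursors (55 of 78, 0.17, 0.07 to 0.26). Ribosomal proteins, a measure of cytoplasmic RNA, went the same way as these 2 lists in those classes: lower in astrocytes (81 of 81) and fibroblasts (79 of 81, -0.45) and higher in oligodendrocyte precursors (58 of 81, 0.08). They were also lower in GABAergic neurons (80 of 81, -0.55). Heat shock genes were lower as well where ribosomal medians lay near 0. In microglia 16 of 18 were lower (-0.19, ribosomal -0.01), in endothelial cells 14 of 18 (-0.12, ribosomal 0.01) and in oligodendrocytes 15 of 18 (-0.20, ribosomal -0.05). Evening clock genes were higher in 7 of 7 members in endothelial cells (median 0.50, 0.39 to 0.58), among them Dbp (0.49) and Per3 (0.57).

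Zbtb16 and Fkbp5 were higher in the fluconazole library in endothelial cells (2.02 and 1.00) and oligodendrocytes (1.78 and 1.47), and Sgk1 in oligodendrocytes (2.04) but not in endothelial cells (-0.07). Free RNA is argued against: Zbtb16 gained 150 CPM in endothelial cells and 1.96 CPM in microglia, which is 1.31% of that gain. Transcription that answers glucocorticoids may account for the pattern as a hypothesis: of 21 other induced genes, 15 of 20 measured were higher in endothelial cells (median 0.31, percentile 100.0) and 17 of 19 in oligodendrocytes (0.32), but 8 of 21 in glutamatergic neurons (-0.18), 8 of 19 in mural cells (-0.20) and 5 of 15 in GABAergic neurons (-0.24), with a median of 0.10 (0.02 to 0.16) in microglia and medians near 0 in astrocytes (0.07, -0.04 to 0.15) and border macrophages (0.03, -0.07 to 0.15). A difference in time of day stays open: the evening less the morning clock median was 0.53 (0.39 to 1.10) in endothelial cells, past the size bound set beforehand, 0.36 (0.01 to 0.67) in oligodendrocytes and 0.56 (0.16 to 0.93) in microglia, but -0.28 (-0.48 to -0.18) in glutamatergic neurons, and the rule that reads such opposite signs as undecided was added after that value was seen. The prediction also asked that the arms move in opposite directions, and nearly all of the endothelial difference came from the evening arm. The treatment itself, handling and differences between mice also stay open and untested.

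Interferon response genes were lower in microglia of the fluconazole library, with a summed log2 ratio of -0.54. Free RNA shared alike by all classes is argued against, since the difference in glutamatergic neurons was 5.29% (0.548 to 10.1) of that in microglia, although it was 43.5% (20.5 to 68.1) in astrocytes and 25.4% (9.96 to 42.5) in oligodendrocytes. A few barcodes are argued against as the whole source: without the 1% of microglia richest in these transcripts, which held 15.5% of them in the vehicle and 9.60% in the fluconazole library, the ratio was -0.45 (-0.51 to -0.39). The makeup of microglial clusters is argued against too, since the list was lower within each of the 3 clusters (-0.52, -0.28 and -0.75, the middle ratio with an interval of -0.40 to -0.16) and their shares alone would give a ratio of 0.007 (0.006 to 0.009). A bound of -0.5 set beforehand for these 2 tests was missed by the -0.45 and by the -0.28, so they speak only against the whole difference, and the treatment, an infection or other state of single mice, and the lower share of blood leukocytes in this library stay open and untested.

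Tmem267 had lower CPM in the fluconazole library in all 12 classes, from 815.6 to 7.94 CPM in striatal-type neurons and from 22.5 to 11.5 CPM in endothelial cells. Free RNA is argued against as the source of the neuronal level, because vehicle endothelial cells held 3.68% of the CPM of vehicle glutamatergic neurons. Vehicle levels were 22.1 to 53.1 CPM in endothelial cells, oligodendrocytes, microglia, mural cells, neuroblast-like cells and border macrophages. Whether free RNA accounts for those low levels was not tested, so the lower CPM there need not be those cells' own. Long genome stretches that differ between the mice stay open for the wider set, which also holds transcripts of other cell types that could hide them: of 170 genes that differed by at least 0.5 the same way in at least 3 classes, 44 had a near neighbour with another symbol stem (members of a gene family not counted) against a median of 47 in random sets (percentile 31.8), in the gene order of GENCODE vM21. A 2nd definition, run after the 1st had given that value, gave 4 of 36 genes against a median of 2 (percentile 70.8). A variant at Tmem267 alone, such as one that differs between the mice, may still account for that gene and was not tested, nor was the treatment.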
